A study of Homo sapiens with 30 samples.

How the data were processed

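RNA sequencing was carried out in HepG2 cells, a line from a human liver cancer, treated for 24 h with 70% ethanol extracts of herbal formulas or with vehicle. Per the labels, the vehicle was 0.1% DMSO, whereas the series text names 2% DMSO. The extracts used here were Bojungikgi-tang, Sayeok-tang, Banhasasim-tang and Yijung-tang, each at 500, 100 and 20 µg/mL per the labels. The series text sets lower doses, based on the IC20, for extracts whose IC20 was under 500 µg/mL, and which extracts this covers was not stated in the sources used here. Directional mRNA libraries were sequenced as 100 bp paired reads, per the labels' protocols. Reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned to hg38 with STAR 2.7.3a and quantified with RSEM 1.3.3, per the submitters' processing notes. The deposited values are expected counts per gene from RSEM, which divides a read that fits several genes among them. Of the values used, 64.5% were 0, and 75.7% of those above 0 were exactly whole, with no tolerance. The annotation release and the strand setting of the counting were not stated in the sources used here.

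The deposited table held 60675 genes and 267 columns, and the 30 columns of this series were used. The other 237 columns belonged to other series and were not used. Samples were placed in 13 groups by formula and dose from their titles and treatment labels. The vehicle group and each dose of Bojungikgi-tang and Sayeok-tang held 3 libraries, each dose of Banhasasim-tang held 2, and each dose of Yijung-tang held 1. The descriptions of 6 libraries (replicate 3 of each dose of Banhasasim-tang and Yijung-tang) name batch D where their titles name batch E. Totals of expected counts ranged from 23899013 to 32205009 per library. Gene symbols were taken from a table pairing identifiers with symbols and from GENCODE release 29, and 41706 identifiers (68.7%) received a symbol, of which 497 came from GENCODE alone. Positions are in GRCh38 coordinates from GENCODE release 29.

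Expected counts were rounded and tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling) in R 4.3.3. One model with a mean per group was fitted to the 27 libraries of the 10 replicated groups, which left 17 residual degrees of freedom. Genes were kept by filterByExpr, and 16014 were tested. Adjusted p values are from the Benjamini-Hochberg method over these genes in each comparison, and a gene was called changed at an adjusted p under 0.05. The 15 comparisons were each dose of the 3 replicated formulas against vehicle, 500 against 20 µg/mL within each formula, and each pair of formulas at 500 µg/mL. Log2 changes carry the standard error of the fit, and group values are CPM with TMM scaling as mean ± SD. The common dispersion was 0.00204, a coefficient of variation between replicates of 4.52%. Counts from reads without molecular identifiers are not independent molecules, so this spread includes more than counting error. The labels name no separate cultures for the replicates, so the p values measure only the spread between these libraries.

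The genes named in the text followed a rule fixed before the data were examined. In each comparison of 500 µg/mL with vehicle, the 10 genes with the largest change in each direction were named. They were taken from changed genes with a symbol, a mean of at least 5 CPM in either group, and no overlap between the libraries of the groups. The rule named 3 genes per direction in the other comparisons of doses and 5 per direction between formulas. One gene that it named between formulas is not reported here. For Yijung-tang it named the 10 largest differences in each direction at 500 µg/mL among genes of at least 5 CPM that lay outside the vehicle range, on the same side, at 500 and 100 µg/mL. Members of gene lists given as examples were chosen after their values were seen. Genes that share reads with near-identical copies, readthrough transcripts or pseudogenes are reported as uncertain.

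Gene lists were written from general knowledge before testing. The 33 lists were targets of AhR, NRF2, PXR and CAR, LXR, PPARA with fatty acid oxidation, p53, the glucocorticoid receptor, Wnt with beta-catenin, and ATF4 with the integrated stress response. Other lists held genes of cholesterol synthesis and uptake, fatty acid synthesis, bile acids with FXR targets, gluconeogenesis with FOXO and insulin targets, hypoxia with glycolysis, and oxidative phosphorylation (OXPHOS) encoded in the nucleus or in mitochondria. Lists of ER chaperones with the unfolded protein response, heat shock, tRNA synthetases, cytosolic ribosomal proteins, autophagy with lysosomes, and metallothioneins with the zinc response were also used. The last of these had 9 measured members, of which 7 were metallothionein genes, and its counts and medians are given under the name metallothioneins. The rest held DNA replication, mitosis, immediate early genes, secreted hepatocyte proteins, acute phase with IL6 and STAT3, NF-kB, interferon, TGF-beta with matrix, other cell types, other epithelial lines, and RNA quality. Lists may share genes, such as ABCC2 (NRF2, and PXR with CAR), UGT1A1 (AhR, and PXR with CAR) and NQO1 (AhR and NRF2), so their tests are not independent. Each list was tested with camera (limma 3.58.1) at its preset correlation between genes, with Benjamini-Hochberg adjustment over the 33 lists and 15 comparisons. Counts of changed members use the adjustment over all tested genes, and counts adjusted over the list alone stand beside them where they differ.

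Yijung-tang had 1 library per dose and was not tested. Its values are the difference in log2 CPM (prior count 2) from the mean of the vehicle libraries, and list medians were ranked among 10000 random lists of genes matched on expression. Gene counts for it include genes at least 2-fold from the vehicle mean and outside the range of the 3 vehicle libraries.

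Responses shared between formulas were set against 20 simulations in which no formula had an effect and the vehicle libraries were shared. A test of interaction gave the genes whose change between 20 and 500 µg/mL differed between formulas. The scripts were tested on simulated data made with the means and library sizes of these samples. All genes were given the same dispersion, and changed genes were drawn only from those above a floor of expression. For Bojungikgi-tang at 500 µg/mL, 84% of the genes changed 1.25-fold were recovered and 100% of those changed 2-fold. For Banhasasim-tang, with 2 libraries, 76% were recovered at 1.25-fold.

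The alternatives tried were DESeq2 1.42.0 scaling and its Wald test, limma-voom, 2 other filters, fits of 2 groups at a time, a fit with the replicate number as a term, leaving out 1 library at a time, and leaving out the libraries described as batch D. For lists, camera with an estimated correlation and fry were tried, and for Yijung-tang prior counts of 0.5 and 5. After the data were seen, 3 alternatives were added. These were a correction of GC content and transcript length per library (lowess span 0.2), a fit without the mitochondrially encoded genes, and the 8 libraries at 20 µg/mL of the replicated formulas as reference instead of vehicle. The tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The wortmannin control and water extracts named in the series text were not analysed here.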

Results

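RNA abundance was measured by sequencing in 30 libraries of HepG2 cells, a human liver cancer line, after 24 h with vehicle (DMSO) or with ethanol extracts of 4 herbal formulas used for digestive complaints. The series was made to turn digestive herbal medicines into transcriptome data. Vehicle had 3 libraries, Bojungikgi-tang and Sayeok-tang had 9 each, Banhasasim-tang had 6 and Yijung-tang had 3, spread over 500, 100 and 20 µg/mL. Totals of expected counts lay between 23899013 and 32205009 per library. The comparisons asked which genes each extract changed against vehicle, which of them depended on dose, and which differed between formulas. All tests below are edgeR quasi-likelihood tests for single genes and camera for lists, with Benjamini-Hochberg adjustment, and log2 changes are given ± standard error.

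The aryl hydrocarbon receptor (AhR) gene CYP1A1, which encodes an enzyme that oxidises polycyclic aromatic compounds, rose with dose in every replicated formula. Genes under NRF2, the factor that answers electrophiles and oxidants, rose at 500 µg/mL in all of them, and genes of cholesterol synthesis and of secreted liver proteins fell between 20 and 500 µg/mL. With Banhasasim-tang, ATF4 stress genes, immediate early genes and mitochondrial ribosomal RNA rose and mitotic genes fell, each more than with Bojungikgi-tang or Sayeok-tang at 500 µg/mL. Metallothioneins, which bind zinc and copper, fell between 20 and 500 µg/mL in each replicated formula. For Banhasasim-tang sharing of reads between their copies could not be told apart from a change of the genes. Beside these groups, the 3 vehicle libraries stood apart from every extract library. On the first principal component (19.5% of variance) the vehicle libraries lay between -35.9 and -32.2, and the nearest extract library lay at -14.4. The log2 changes at 20 µg/mL against vehicle ran with the GC content of the genes, with a Spearman correlation across genes of 0.632 for Bojungikgi-tang, 0.649 for Sayeok-tang and 0.613 for Banhasasim-tang. Between 500 and 20 µg/mL the same correlation was 0.0724, 0.0919 and 0.053. Counts against vehicle are therefore given together with counts after correction for GC content and length. Counts against the 8 libraries at 20 µg/mL of the replicated formulas are given as well. Both settings were chosen after the data were seen. Corrected counts include genes not called before the correction. List tests against vehicle are given without the correction.

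**Figure D1:**
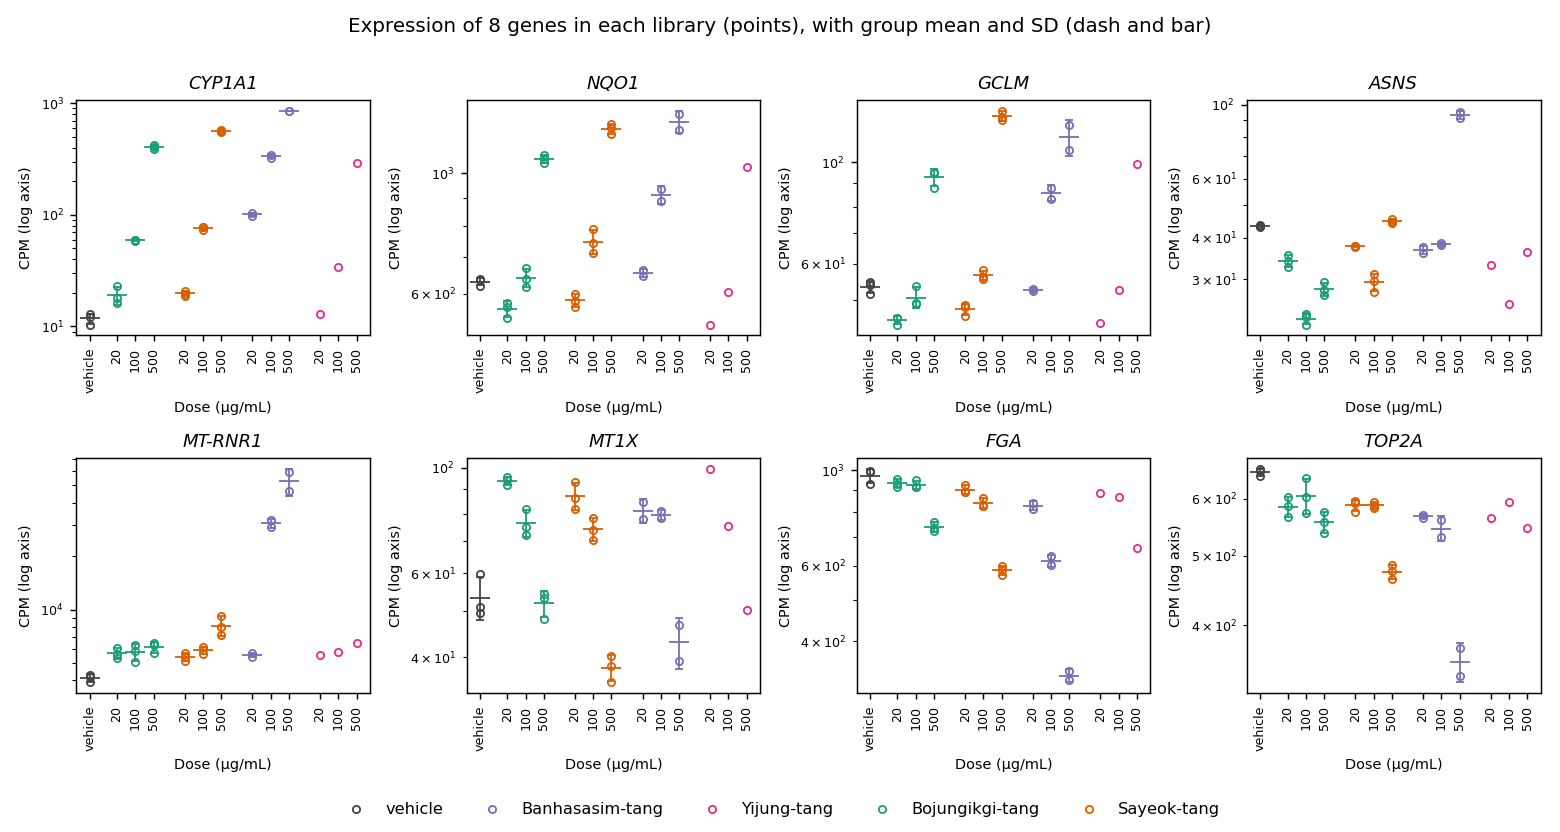
CPM on a log axis of 8 genes in each library, with dashes for group means and bars for SD, from vehicle through 20, 100 and 500 µg/mL of each formula. CYP1A1 climbed from 11.8 CPM in vehicle to 850.6 CPM with Banhasasim-tang at 500 µg/mL, and MT-RNR1 from 4123 to 52850 CPM.

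With Bojungikgi-tang at 500 µg/mL, the AhR targets CYP1A1, CYP1A2 and ALDH3A1 and the NRF2 targets NQO1, GCLM and AKR1B10 rose, while HMGCS1 of cholesterol synthesis fell. LRRN4, which encodes a leucine-rich membrane protein, HES4, a transcriptional repressor, AQP3, a channel for water and glycerol, and SOX18, a transcription factor of vessels, were also among the largest rises. SERPINA7, which encodes the thyroxine carrier of plasma, and SGK1, a kinase induced by serum and glucocorticoids, were among the largest falls. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) rose from 11.8 ± 1.27 CPM in vehicle (SD, n = 3) to 404.1 ± 18.8 CPM (SD, n = 3), a log2 change of 5.10 ± 0.082 (edgeR adjusted p = 2.93e-22). CYP1A2, its neighbour with a related substrate range, rose by 4.42 ± 0.39 (edgeR adjusted p = 1.1e-10). LRRN4 (ENSG00000125872, chromosome 20, 6040778 to 6054049) rose by 3.51 ± 0.184 from 0.438 ± 0.165 to 5.10 ± 0.254 CPM (SD, n = 3 each). HES4 rose by 2.54 ± 0.134, MYOF by 1.70 ± 0.129, AQP3 by 1.66 ± 0.0912, TMEM160 by 1.60 ± 0.342, SLC5A11 by 1.53 and SOX18 by 1.48 ± 0.0888. SULT1A3 (1.49), which shares reads with a near-identical copy, and AC009086.2 (1.42), which overlaps another transcript, are uncertain. SERPINA7 (ENSG00000123561, chromosome X, 106032442 to 106038738) fell by 1.08 ± 0.0465 from 134.1 ± 1.26 to 63.4 ± 2.53 CPM (SD, n = 3 each), and SGK1 fell by 1.08 ± 0.044. PLPPR1 (-1.15), the sodium channel gene SCN1A (-1.03), KLHL24 (-1.02), the amino acid transporter gene SLC6A14 (-1.0), MATN3 (-1.0) and the receptor gene PDGFRB (-0.99) fell as well. The pseudogene PTMAP5 (-1.43) and the signal recognition particle RNA gene RN7SL2 (-1.27 ± 0.482, edgeR adjusted p = 0.0387) are uncertain. RN7SL2 lost its call without vehicle replicate 1 or 2 or without any of the 3 treated libraries (-1.13 to -1.45).

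Of the 8 AhR targets measured, 6 rose and 1 fell with Bojungikgi-tang at 500 µg/mL (median log2 change 2.20, camera adjusted p = 3.8e-20). NRF2 targets rose in 21 of 24 cases and fell in 1 (median 0.594, camera adjusted p = 2.6e-42). NQO1 was at 0.75 ± 0.038, GCLM at 0.80 ± 0.046 and the aldo-keto reductase gene AKR1B10 at 1.41 ± 0.046. In the cholesterol list 16 of 24 genes fell and 3 rose (17 and 4 adjusted over the list alone, median -0.212, camera adjusted p = 5.4e-06), with HMGCS1 at -0.70 ± 0.041. Among 28 secreted hepatocyte proteins, 15 fell and 6 rose (16 and 6 adjusted over the list alone, median -0.197, camera adjusted p = 0.0011), among them FGG (-0.51) and TTR (-0.49). That call was lost with an estimated correlation (adjusted p = 0.16). The ATF4 list did not move as a group (9 of 27 higher and 11 lower, 9 and 12 adjusted over the list alone, median 0.0121, camera adjusted p = 0.96). Neither did mitosis (10 of 28 higher and 5 lower, median 0.0325, camera adjusted p = 0.41). Against vehicle 7383 genes changed in edgeR, 3819 higher and 3564 lower, of which 323 changed at least 2-fold. After GC and length correction the count was 5399, of which 3897 were also called before it. Against the 8 libraries at 20 µg/mL it was 2900, with 83 at least 2-fold, HES4 (0.028), TMEM160 (0.012), SULT1A3 (0.39), SOX18 (0.031) and RN7SL2 (-0.063) lost their calls, and so did AC009086.2 (-0.16) and PTMAP5 (0.16), with a change of sign.

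At the lower doses of Bojungikgi-tang the AhR response shrank, with CYP1A1 at 2.33 ± 0.0834 at 100 µg/mL (edgeR adjusted p = 4.46e-15) and at 0.69 ± 0.093 at 20 µg/mL (edgeR adjusted p = 4.9e-06). CYP1A2 did not pass at 100 µg/mL (1.02 ± 0.61, edgeR adjusted p = 0.26). C4orf48, which encodes a small secreted peptide, was above vehicle by 3.26 ± 0.202 and HES4 by 2.47 at 100 µg/mL. SEC61G, a subunit of the protein channel of the endoplasmic reticulum, fell by 0.94 ± 0.136, and PTMAP5 by 1.56. The readthrough RPS10-NUDT3 (-0.94, edgeR adjusted p = 0.0184) is uncertain and lost its call without treated replicate 2 (-0.77) or 3 (-0.83) and after GC correction (-0.85). At 20 µg/mL HES4 was 2.48 ± 0.133 above vehicle, AC009086.2 1.56 and TMEM160 1.46. PTMAP5 (-1.70), EEF1A1P6 (-0.98) and RN7SL2 (-1.40, edgeR adjusted p = 0.0293), all uncertain, were lower, and RN7SL2 lost its call without vehicle replicate 1 (-1.41) or 2 (-1.29) or treated replicate 2 (-1.2) or 3 (-1.25). The metallothionein list was above vehicle at 20 µg/mL, with 7 of 9 members higher and 1 lower (7 and 2 adjusted over the list alone, median 0.813, camera adjusted p = 9.6e-08). MT1G was higher by 1.28 ± 0.10 and MT1X by 0.81. NRF2 targets at 20 µg/mL gave 9 higher and 10 lower of 24 (9 and 11 adjusted over the list alone, median -0.101, camera adjusted p = 0.86).

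The lists gave few calls that held at the lower doses of Bojungikgi-tang. AhR targets at 100 µg/mL had 2 members higher and 1 lower of 8 (median 0.733, camera adjusted p = 0.00022), and at 20 µg/mL 2 higher and 1 lower (median 0.105, camera adjusted p = 0.67). With the 20 µg/mL libraries as reference no AhR target was called at 100 µg/mL (median 0.203). NRF2 targets at 100 µg/mL (10 of 24 higher, 4 lower, median 0.0242, camera adjusted p = 0.024) lost the call with an estimated correlation (adjusted p = 0.15). Metallothioneins at 100 µg/mL (6 of 9 higher, 1 lower, median 0.462, camera adjusted p = 0.019) did so too (adjusted p = 0.24 with an estimated correlation). Mitotic genes were higher at 100 µg/mL in 15 of 28 cases and lower in 1 (15 and 2 adjusted over the list alone, median 0.0956, camera adjusted p = 0.0011), with an adjusted p = 0.077 with an estimated correlation. DNA replication genes were higher in 12 of 29 cases and lower in 2 (median 0.067, camera adjusted p = 0.011). LXR targets, which oxysterols induce, were higher at 20 µg/mL in 5 of 9 cases and lower in 1 (5 and 2 adjusted over the list alone, median 0.174, camera adjusted p = 0.011). Before correction, medians of genes grouped by GC content ran from -0.196 to 0.348 at this dose. Small list medians against vehicle may therefore carry the GC trend. In edgeR 6293 genes changed at 100 µg/mL and 6155 at 20 µg/mL, against 3459 and 2718 after GC and length correction. With the 20 µg/mL libraries as reference 58 genes changed at 100 µg/mL, the calls of C4orf48 (0.11), CYP1A1 (0.58), SEC61G (-0.041) and RPS10-NUDT3 (-0.16) were lost, as were those of HES4 (-0.040) and PTMAP5 (0.036), with a change of sign. This reference pools the formulas at 20 µg/mL, including the Banhasasim-tang libraries with CYP1A1 at 100.8 ± 3.43 CPM (SD, n = 2).

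Between 500 and 20 µg/mL of Bojungikgi-tang, where no vehicle library enters, the AhR and NRF2 genes rose and metallothioneins, secreted liver proteins and cholesterol genes fell. CYP1A1 rose by 4.41 ± 0.0772 (edgeR adjusted p = 2.02e-21), LRRN4 by 2.7 and AQP3 by 1.66. NGFR, which encodes a neurotrophin receptor, fell by 1.80 ± 0.171 (edgeR adjusted p = 2.63e-09), SERPINA7 by 0.91, and MT1F by 1.02 ± 0.0555. Metallothionein copies share reads, so their single values are uncertain. AhR targets rose in 6 of 8 cases (6 rose and 1 fell adjusted over the list alone, median 1.89, camera adjusted p = 3.9e-55). NRF2 targets rose in 21 of 24 (23 adjusted over the list alone, median 0.473, camera adjusted p = 4e-118), with GCLM at 1.04 and NQO1 at 0.92. Metallothioneins fell in 7 of 9 cases and rose in 1 (8 and 1 adjusted over the list alone, median -0.785, camera adjusted p = 5.1e-19). Secreted hepatocyte proteins fell in 18 of 28 cases and rose in 2 (21 and 2 adjusted over the list alone, median -0.23, camera adjusted p = 6.5e-13), with the heme carrier HPX at -0.72. Cholesterol genes fell in 16 of 24 cases (18 adjusted over the list alone, median -0.21, camera adjusted p = 3.8e-16), with HMGCS1 at -0.44. PXR and CAR targets, which handle drugs, rose in 4 of 11 cases and fell in 2 (5 and 2 adjusted over the list alone, median 0.092, camera adjusted p = 8e-05), with the transporter gene ABCC2, which is also in the NRF2 list, at 0.73. Glucocorticoid receptor targets fell in 3 of 11 cases and rose in 1 (4 and 1 adjusted over the list alone, median -0.108, camera adjusted p = 0.0018). In edgeR 2433 genes changed, 1290 higher and 1143 lower, and 92 changed at least 2-fold.

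Sayeok-tang at 500 µg/mL raised AhR and NRF2 targets, with AKR1B10 and AQP3 among its largest rises. CPT1A, which brings fatty acids into mitochondria, and the stress hormone gene GDF15 also rose. HMGCS1, the fibrinogen genes FGA and FGG, the Wnt inhibitor gene DKK1 and SERPINA7 fell. CYP1A1 rose by 5.58 ± 0.0825 to 564.1 ± 14.7 CPM (SD, n = 3; edgeR adjusted p = 2.39e-23). AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408) rose by 1.89 ± 0.0462 from 97.2 ± 1.60 to 359.2 ± 3.85 CPM (SD, n = 3 each; edgeR adjusted p = 1.24e-23). AQP3 (ENSG00000165272, chromosome 9, 33441154 to 33447633) rose by 2.40 ± 0.0856 from 3.87 ± 0.150 to 20.4 ± 1.04 CPM (SD, n = 3 each). LRRN4 rose by 3.78 ± 0.178, HES4 by 2.48, the inositol transporter gene SLC5A11 by 2.11, the phosphatase gene DUSP13 by 2.08, the imprinted gene PHLDA2 by 1.96, MYOF by 1.90 and SULT1A3, uncertain, by 1.92. DKK1 fell by 1.2 ± 0.0497 from 105.8 ± 4.60 to 45.9 ± 2.38 CPM (SD, n = 3 each). The sodium channel genes SCN1A (-1.54) and SCN9A (-1.22), PLPPR1 (-1.41), SERPINA7 (-1.31), MT1F (-1.28), the betaine transporter gene SLC6A12 (-1.22) and SGK1 (-1.22) fell as well. PTMAP5 (-1.39) and the readthrough PEDS1-UBE2V1 (-1.61, edgeR adjusted p = 0.00804) are uncertain.

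AhR targets rose in 6 of 8 cases and fell in 1 with Sayeok-tang at 500 µg/mL (median 2.29, camera adjusted p = 1.2e-17), with ALDH3A1 at 2.75. NRF2 targets rose in 22 of 24 cases (median 0.854, camera adjusted p = 1.3e-65), with GCLM at 1.24 ± 0.045 and the sulfiredoxin gene SRXN1 at 1.2. Cholesterol genes fell in 18 of 24 cases and rose in 5 (median -0.265, camera adjusted p = 4.3e-06), with HMGCS1 at -0.91 ± 0.041. Secreted hepatocyte proteins fell in 16 of 28 cases and rose in 6 (median -0.329, camera adjusted p = 4.5e-07), with FGG at -0.91 and FGA at -0.73. PXR and CAR targets rose in 7 of 11 cases and fell in 3 (median 0.321, camera adjusted p = 0.0042). The ATF4 list (14 of 27 higher, 7 lower, median 0.12, camera adjusted p = 0.003), which includes SLC7A11 (0.84), had an adjusted p = 0.053 with an estimated correlation. Metallothioneins (6 of 9 lower, 2 higher, median -0.491, camera adjusted p = 0.0011) had an adjusted p = 0.12 with an estimated correlation. Immediate early genes (8 of 19 higher, median 0.207, camera adjusted p = 0.00094) had an adjusted p = 0.12 with an estimated correlation. Mitotic genes (17 of 28 lower, 5 higher, median -0.127, camera adjusted p = 0.031) had an adjusted p = 0.23 with an estimated correlation. In edgeR 8032 genes changed, 4097 higher and 3935 lower, and 523 changed at least 2-fold; the count was 6515 after GC and length correction. With the 20 µg/mL libraries as reference 5069 genes changed, 236 of them at least 2-fold, PEDS1-UBE2V1 (-0.90) lost its call, and so did HES4 (-0.030) and PTMAP5 (0.21), with a change of sign.

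At 100 µg/mL of Sayeok-tang CYP1A1 was above vehicle by 2.69 ± 0.0826 (edgeR adjusted p = 4.58e-16), CYP1A2 by 2.02 ± 0.53, C4orf48 by 3.28 and HES4 by 2.60. CYP3A7, a fetal liver oxidase, fell by 0.93 ± 0.109 (edgeR adjusted p = 7.19e-08), KLHL24 by 0.91 and PTMAP5 by 1.43. Of the AhR targets, 4 of 8 rose (median 0.844, camera adjusted p = 1.2e-06). Of the NRF2 targets, 15 of 24 rose and 2 fell (median 0.187, camera adjusted p = 4.5e-08). DNA replication genes rose in 12 of 29 (13 adjusted over the list alone, median 0.0591, camera adjusted p = 0.0028). Metallothioneins (6 of 9 higher, 1 lower, median 0.432, camera adjusted p = 0.022) had an adjusted p = 0.25 with an estimated correlation. At 20 µg/mL C4orf48 was 3.24 above vehicle, HES4 2.58 ± 0.132 and TMEM160 1.77, while CYP1A1 rose by 0.74 ± 0.092 (edgeR adjusted p = 1.8e-06) and CYP1A2 did not pass (-1.25, edgeR adjusted p = 0.35). Metallothioneins rose in 7 of 9 cases and fell in 1 (median 0.656, camera adjusted p = 7.9e-06), with MT1G at 1.13. PTMAP5 (-1.60) and the readthroughs MSANTD3-TMEFF1 (-1.04) and RPS10-NUDT3 (-0.98) are uncertain, and RPS10-NUDT3 lost its call without treated replicate 1 (-0.78) or 3 (-0.85) and after GC correction (-0.89). AhR targets at 20 µg/mL (1 of 8 higher, 1 lower, median 0.0357, camera adjusted p = 0.89) did not move as a group. Neither did NRF2 targets (8 of 24 higher, 9 lower, 9 and 10 adjusted over the list alone, median -0.0326, camera adjusted p = 0.65). In edgeR 6234 genes changed at 100 µg/mL and 5814 at 20 µg/mL, against 3268 and 1925 after GC and length correction. With the 20 µg/mL libraries as reference 264 changed at 100 µg/mL, the calls of C4orf48 (0.13), CYP1A1 (0.95), CYP1A2 (1.3), HES4 (0.095) and KLHL24 (-0.29) were lost, as was that of PTMAP5 (0.17), with a change of sign. This reference includes the Banhasasim-tang libraries, with CYP1A1 at 100.8 CPM. Within Sayeok-tang CYP1A1 stood at 19.8 ± 0.976 CPM at 20 µg/mL and at 76.3 ± 3.00 CPM at 100 µg/mL (SD, n = 3 each).

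From 20 to 500 µg/mL of Sayeok-tang, CYP1A1 and the NRF2 genes rose and the metallothionein, secreted protein and cholesterol genes fell. ABCC2, an exporter of conjugated drugs and bilirubin, and ALDH1L2, a mitochondrial folate enzyme, also rose. CYP1A1 rose by 4.83 ± 0.0772 (edgeR adjusted p = 1.33e-22), LRRN4 by 2.76, AQP3 by 2.25, AKR1B10 by 2.00 and GCLM by 1.40. MT1F fell by 1.65 ± 0.0584 from 71.7 ± 3.67 to 22.8 ± 0.875 CPM (SD, n = 3 each; edgeR adjusted p = 7.12e-20), MT1G by 1.44 ± 0.106 and SCN1A by 1.40. Metallothioneins fell in 7 of 9 cases and rose in 1 (median -1.2, camera adjusted p = 2e-20). AhR targets rose in 6 of 8 and fell in 1 (7 and 1 adjusted over the list alone, median 2.14, camera adjusted p = 1.2e-36). NRF2 targets rose in 23 of 24 (median 0.723, camera adjusted p = 2.2e-127). Secreted hepatocyte proteins fell in 21 of 28 cases and rose in 3 (22 and 4 adjusted over the list alone, median -0.325, camera adjusted p = 4.9e-15), with HPX at -1.06. Cholesterol genes fell in 18 of 24 and rose in 1 (19 and 1 adjusted over the list alone, median -0.247, camera adjusted p = 1.3e-14). PXR and CAR targets rose in 8 of 11 cases and fell in 1 (median 0.369, camera adjusted p = 4.7e-08), with ABCC2, shared with the NRF2 list, at 0.99. ER chaperones rose in 12 of 20 cases and fell in 3 (14 and 3 adjusted over the list alone, median 0.151, camera adjusted p = 0.0024), with DNAJB9 at 0.45. The tRNA synthetases rose in 10 of 13 (median 0.144, camera adjusted p = 0.0002). Wnt targets fell in 8 of 14 cases and rose in 1 (median -0.232, camera adjusted p = 1.3e-06). Mitotic genes fell in 16 of 28 (18 adjusted over the list alone, median -0.145, camera adjusted p = 5.8e-05). Acute phase genes fell in 5 of 13 and rose in 2 (median -0.0608, camera adjusted p = 0.019). Autophagy genes rose in 9 of 28 cases and fell in 3 (9 and 4 adjusted over the list alone, median 0.0474, camera adjusted p = 0.0011). In edgeR 4338 genes changed, 2278 higher and 2060 lower, and 236 changed at least 2-fold.

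Banhasasim-tang at 500 µg/mL gave the largest AhR response, and AHRR, the repressor that the receptor itself induces, was among its largest rises. It also raised ASNS, which makes asparagine, the cystine transporter gene SLC7A11 and GDF15, all targets of the stress factor ATF4. EGR1 and FOSL1, which growth signals induce early, rose, and TOP2A and CDK1, needed for chromosome separation and entry into mitosis, fell. The 12S ribosomal RNA of mitochondria, MT-RNR1, rose, and the fibrinogen gene FGA and the kininogen gene KNG1 fell. CYP1A1 rose by 6.17 ± 0.086 to 850.6 ± 1.78 CPM (SD, n = 2; edgeR adjusted p = 6.45e-24), and CYP1A2 by 5.11 ± 0.38. MT-RNR1 (ENSG00000211459, mitochondrial genome, 648 to 1601) rose by 3.68 ± 0.116 from 4123 ± 199.2 CPM (SD, n = 3) to 52850 ± 9209 CPM (SD, n = 2; edgeR adjusted p = 7.88e-15). IGFBP1 (ENSG00000146678, chromosome 7, 45888357 to 45893668), which encodes a carrier of insulin-like growth factors, rose by 2.74 ± 0.116 from 38.8 ± 4.13 to 259.2 ± 14.8 CPM (edgeR adjusted p = 4.9e-13). FGA (ENSG00000171560, chromosome 4, 154583126 to 154590766) fell by 1.55 ± 0.0413 from 970.9 ± 37.7 to 332.3 ± 11.5 CPM (edgeR adjusted p = 3.7e-23). LRRN4 rose by 4.10 ± 0.187, LRRC25 by 3.73, AHRR by 3.70 ± 0.209, the neural transcription factor gene NPAS1 by 3.18, AQP3 by 3.15 ± 0.0883, PHLDA2 by 2.69 and HES4 by 2.58. SLC6A12 (-2.13), KITLG (-1.67), which encodes stem cell factor, KNG1 (-1.65), SLC6A14 (-1.51) and SERPINA7 (-1.50) fell. ACSM2A (-1.80) and ACSM2B (-1.68), near-identical copies, the pseudogene ACSL3P1 (-1.59) and the antisense transcript MVP-DT (-1.62) are uncertain.

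ATF4 targets rose in 22 of 27 cases and fell in 2 with Banhasasim-tang at 500 µg/mL (23 and 2 adjusted over the list alone, median 0.82, camera adjusted p = 1.1e-27). GDF15 was at 2.20 ± 0.047, SLC7A11 at 1.74 and ASNS at 1.11 ± 0.047. Immediate early genes rose in 17 of 19 cases (median 0.826, camera adjusted p = 1.6e-13), with FOSL1 at 1.57 ± 0.13 and EGR1 at 1.18 ± 0.097. The tRNA synthetases rose in 10 of 13 (10 rose and 1 fell adjusted over the list alone, median 0.50, camera adjusted p = 2.9e-10). Mitotic genes fell in 25 of 28 cases (26 adjusted over the list alone, median -0.443, camera adjusted p = 4.4e-16), with TOP2A at -0.88 ± 0.044 and CDK1 at -0.84. DNA replication genes fell in 20 of 29 cases and rose in 3 (21 and 3 adjusted over the list alone, median -0.268, camera adjusted p = 1.4e-05), with TK1, which salvages thymidine, at -0.70. AhR targets rose in 6 of 8 cases (median 2.86, camera adjusted p = 8.3e-20). NRF2 targets rose in 22 of 24 and fell in 1 (22 and 2 adjusted over the list alone, median 0.869, camera adjusted p = 1.6e-49). Cholesterol genes fell in 21 of 24 cases and rose in 3 (median -0.375, camera adjusted p = 1.6e-10). Secreted hepatocyte proteins fell in 15 of 28 and rose in 4 (16 and 4 adjusted over the list alone, median -0.246, camera adjusted p = 2.1e-09), with FGG at -1.37 ± 0.047 and ALB at -0.64. NF-kB genes (6 of 13 higher, 1 lower, median 0.544, camera adjusted p = 0.015) had an adjusted p = 0.12 with an estimated correlation. Autophagy (14 of 28 higher, 7 lower, median 0.135, camera adjusted p = 0.027) had an adjusted p = 0.12 with an estimated correlation. TGF-beta with matrix (9 of 17 higher, 3 lower, median 0.12, camera adjusted p = 0.0016) had an adjusted p = 0.076 with an estimated correlation. The NF-kB median was 0.111 with the 20 µg/mL libraries as reference. In edgeR 8368 genes changed, 4287 higher and 4081 lower, and 830 changed at least 2-fold. The count was 7234 after GC and length correction and 5815 (420 at least 2-fold) against the 20 µg/mL libraries, where HES4 (0.068) lost its call.

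**Figure D2:**
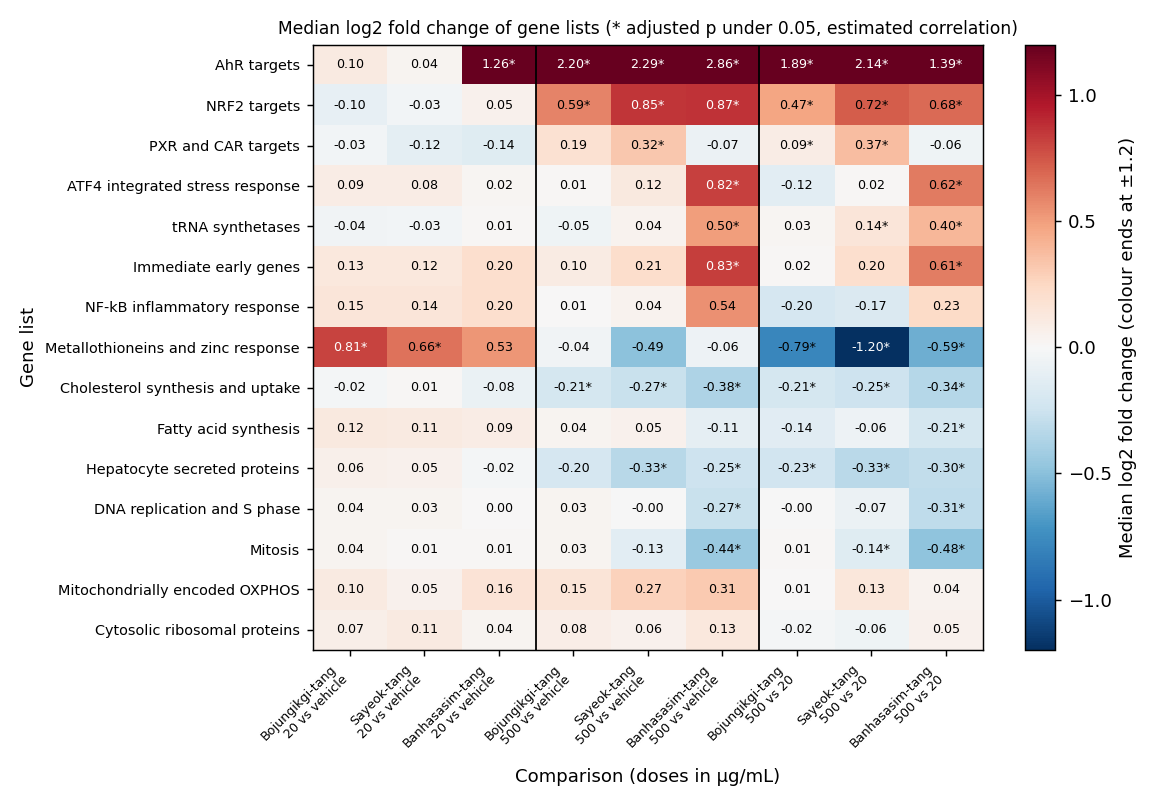
Heat map of the median log2 change of 15 gene lists in 9 comparisons (20 and 500 µg/mL against vehicle, and 500 against 20 µg/mL, for 3 formulas), with colour ends at ±1.2. Stars mark camera calls that held with an estimated correlation, and ATF4 targets reached a median of 0.82 with Banhasasim-tang at 500 µg/mL against 0.0121 with Bojungikgi-tang.

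With Banhasasim-tang the AhR and NRF2 lists were also higher at 100 µg/mL, and the AhR list at 20 µg/mL. CYP1A1 rose by 4.83 ± 0.0847 to 335.1 ± 14.4 CPM (SD, n = 2; edgeR adjusted p = 2.12e-21) at 100 µg/mL. The rise was 3.09 ± 0.0868, to 100.8 ± 3.43 CPM (SD, n = 2; edgeR adjusted p = 6.53e-17), at 20 µg/mL. CYP1A2 rose by 3.75 and by 2.31 ± 0.56 at these doses, and HES4 was 2.40 and 2.44 above vehicle. MT-RNR1 at 100 µg/mL was 2.89 ± 0.113 above vehicle, at 30560 ± 1949 CPM (SD, n = 2). SOX18 was higher by 1.53 at 20 µg/mL, and SEC61G (-1.14), PTMAP5 (-1.45) and NDUFA1 (-0.99, edgeR adjusted p = 0.0101), a subunit of respiratory complex I, were lower. NDUFA1 lost its call without replicate 3, described as batch D (-0.90). At 100 µg/mL PTMAP5 (-1.51), MVP-DT (-1.29) and PEDS1-UBE2V1 (-1.60, edgeR adjusted p = 0.0249), all uncertain, were lower. PEDS1-UBE2V1 lost its call without vehicle replicate 1 (-1.56) or 2 (-1.52) or treated replicate 2 (-1.03).

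At 100 µg/mL of Banhasasim-tang 6 of 8 AhR targets rose (median 1.86, camera adjusted p = 2.2e-19), and 4 of 8 rose at 20 µg/mL (median 1.26, camera adjusted p = 2.6e-07). Of the NRF2 targets, 20 of 24 rose and 2 fell at 100 µg/mL (21 and 2 adjusted over the list alone, median 0.524, camera adjusted p = 1.5e-30), with GCLM at 0.68. Immediate early genes rose in 11 of 19 cases (12 adjusted over the list alone, median 0.55, camera adjusted p = 1.4e-07). ATF4 targets rose in 11 of 27 and fell in 5 (median 0.131, camera adjusted p = 0.00064). At 20 µg/mL the NRF2 list (11 of 24 higher, 4 lower, median 0.0526, camera adjusted p = 0.0053) had an adjusted p = 0.087 with an estimated correlation. Metallothioneins at 100 µg/mL (5 of 9 higher, 1 lower, median 0.578, camera adjusted p = 0.0083) had an adjusted p = 0.19 with an estimated correlation. The same held at 20 µg/mL (6 of 9 higher, 2 lower, median 0.532, camera adjusted p = 0.009, adjusted p = 0.19 with an estimated correlation). In edgeR 6747 genes changed at 100 µg/mL (4351 without treated replicate 2) and 6458 at 20 µg/mL, against 5485 and 3170 after GC and length correction. With the 20 µg/mL libraries as reference 2278 changed at 100 µg/mL, MVP-DT (-0.62) and PEDS1-UBE2V1 (-0.89) lost their calls, and so did HES4 (-0.11) and PTMAP5 (0.084), with a change of sign.

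Raising Banhasasim-tang from 20 to 500 µg/mL raised ATF4, immediate early, AhR and NRF2 genes and MT-RNR1, and lowered mitotic, DNA replication and secreted protein genes. MT-RNR1 rose by 3.25 ± 0.133 from 5550 ± 170.9 CPM (SD, n = 2; edgeR adjusted p = 1.4e-12), CYP1A1 by 3.08 ± 0.0826 (edgeR adjusted p = 2.84e-18) and AQP3 by 2.80. SLC6A12 fell by 1.80, KNG1 by 1.68 and ACSM2A, uncertain, by 1.59. ATF4 targets rose in 24 of 27 cases and fell in 1 (26 and 1 adjusted over the list alone, median 0.619, camera adjusted p = 1.5e-45). SLC7A11 was at 1.72, GDF15 at 1.69 and ASNS at 1.34. The tRNA synthetases rose in 12 of 13 (13 adjusted over the list alone, median 0.397, camera adjusted p = 7.9e-22). All 28 mitotic genes fell (median -0.483, camera adjusted p = 9.8e-39), with the mitotic kinesin gene KIF20A at -0.86. Of the DNA replication genes, 20 of 29 fell (24 adjusted over the list alone, median -0.309, camera adjusted p = 1.7e-14), with MCM2 at -0.49. Immediate early genes rose in 13 of 19 cases (16 adjusted over the list alone, median 0.613, camera adjusted p = 8e-16). AhR targets rose in 5 of 8 (median 1.39, camera adjusted p = 3.4e-21) and NRF2 targets in 22 of 24 (median 0.68, camera adjusted p = 5.4e-78). Cholesterol genes fell in 20 of 24 cases and rose in 1 (21 and 1 adjusted over the list alone, median -0.342, camera adjusted p = 1.8e-16). Secreted proteins fell in 17 of 28 and rose in 3 (19 and 3 adjusted over the list alone, median -0.30, camera adjusted p = 2.3e-16). Fatty acid synthesis genes fell in 11 of 15 (median -0.207, camera adjusted p = 8.7e-09). Metallothioneins fell in 6 of 9 cases and rose in 1 (median -0.589, camera adjusted p = 9e-06). Acute phase genes fell in 6 of 13 (6 fell and 1 rose adjusted over the list alone, median -0.0989, camera adjusted p = 0.0016). Autophagy genes rose in 12 of 28 cases and fell in 1 (13 and 2 adjusted over the list alone, median 0.141, camera adjusted p = 2.8e-05). TGF-beta with matrix rose in 9 of 17 and fell in 3 (9 and 4 adjusted over the list alone, median 0.145, camera adjusted p = 5.3e-05). In edgeR 3784 genes changed, 1980 higher and 1804 lower, and 275 changed at least 2-fold; without the libraries described as batch D the count was 2347.

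**Figure D3:**
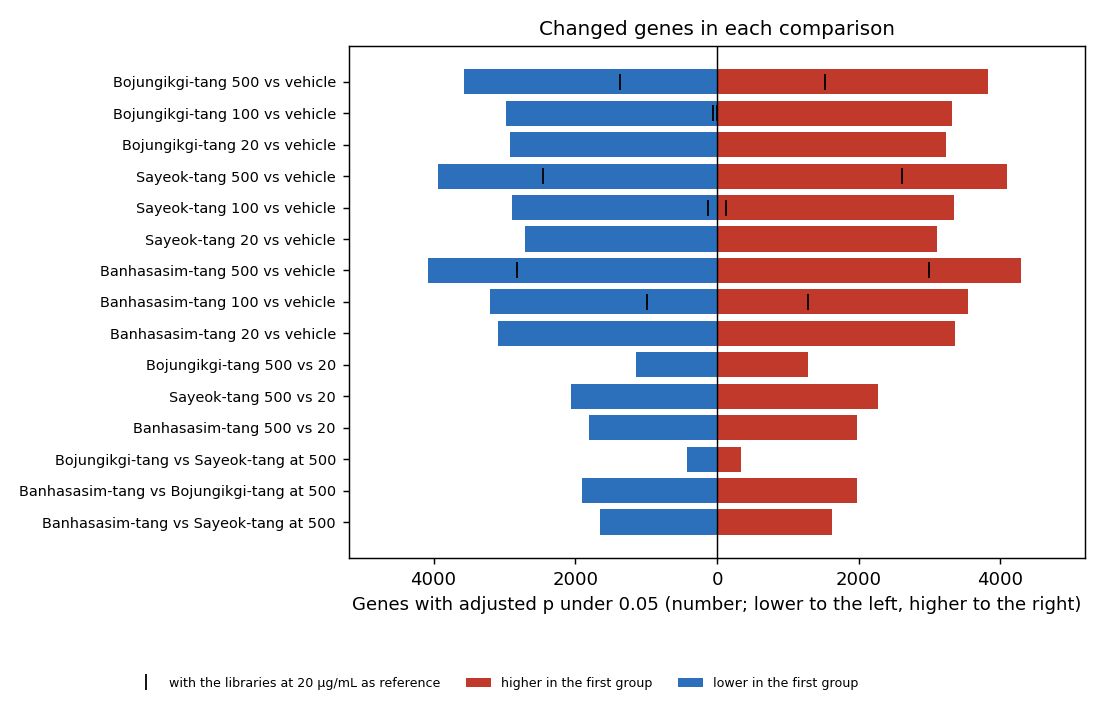
Genes higher and lower in each of the 15 comparisons at an edgeR adjusted p under 0.05, as bars, with marks for the counts against the 8 libraries at 20 µg/mL. At 100 µg/mL of Bojungikgi-tang the count was 6293 against vehicle and 58 against those libraries.

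Between formulas at 500 µg/mL, ATF4 and immediate early genes were higher and mitotic genes lower with Banhasasim-tang than with Bojungikgi-tang or Sayeok-tang, and MT-RNR1, MT-RNR2 and the lipoprotein receptor gene VLDLR were among the largest differences. Against Bojungikgi-tang, MT-RNR1 was higher by 3.10 ± 0.114, MT-RNR2 by 2.29, VLDLR by 2.15, the peptide hormone gene ADM2 by 2.10 ± 0.107 (edgeR adjusted p = 1.36e-15) and IGFBP1 by 2.00. MT-RNR2 (mitochondrial genome, 1671 to 3229) was at 117700 ± 19160 CPM (SD, n = 2) against 24120 ± 1320 CPM (SD, n = 3). FGA was lower by 1.15 ± 0.0407 (edgeR adjusted p = 1.82e-19) and KNG1 by 1.26. GSTA2 (-1.34), ACSL3P1 (-1.42) and HTD2 (-1.21, edgeR adjusted p = 0.0044) are uncertain. HTD2 lost its call without Banhasasim-tang replicate 2 (-0.73) and in a fit of 2 groups (-1.21). ATF4 targets were higher in 24 of 27 cases (26 adjusted over the list alone, median 0.707, camera adjusted p = 2.4e-81). Immediate early genes were higher in 17 of 19 (median 0.63, camera adjusted p = 1.3e-20) and tRNA synthetases in 12 of 13 (median 0.439, camera adjusted p = 6.6e-31). All 28 mitotic genes were lower (median -0.524, camera adjusted p = 3.7e-54), as were 23 of 29 DNA replication genes (25 adjusted over the list alone, median -0.327, camera adjusted p = 2.2e-21). NRF2 targets were higher in 17 of 24 cases (median 0.218, camera adjusted p = 3.5e-15) and AhR targets in 5 of 8 (median 0.297, camera adjusted p = 1.3e-05), with CYP1A1 at 1.07. NF-kB genes were higher in 9 of 13 cases (median 0.37, camera adjusted p = 9.6e-06). TGF-beta with matrix was higher in 9 of 17 and lower in 2 (9 and 3 adjusted over the list alone, median 0.264, camera adjusted p = 4.7e-10). Autophagy was higher in 10 of 28 and lower in 1 (11 and 1 adjusted over the list alone, median 0.0795, camera adjusted p = 0.00023). Cholesterol genes were lower in 17 of 24 cases and higher in 1 (19 and 1 adjusted over the list alone, median -0.183, camera adjusted p = 3.6e-07). Secreted proteins were lower in 13 of 28 and higher in 3 (15 and 3 adjusted over the list alone, median -0.115, camera adjusted p = 8.3e-10). Acute phase genes were lower in 5 of 13 (6 adjusted over the list alone, median -0.0723, camera adjusted p = 0.0042). In edgeR 3884 genes differed, 1980 higher and 1904 lower, and 2438 did so without Banhasasim-tang replicate 2.

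Against Sayeok-tang, Banhasasim-tang had higher MT-RNR1 (2.7), MT-RNR2 (2.04), VLDLR (1.71), AHRR (1.48) and ADM2 (1.39). The iron hormone gene HAMP was lower by 0.97 ± 0.0636, at 56.3 ± 1.23 CPM (SD, n = 2) against 110.1 ± 1.72 CPM (SD, n = 3; edgeR adjusted p = 6.22e-12), and FGA by 0.82. GSTA2 (-1.57), GSTA1 (-1.11) and ACSL3P1 (-1.26) are uncertain. ATF4 targets were higher in 23 of 27 cases (25 adjusted over the list alone, median 0.572, camera adjusted p = 4.6e-60). Immediate early genes were higher in 15 of 19 (16 adjusted over the list alone, median 0.534, camera adjusted p = 2.1e-18). The tRNA synthetases were higher in 10 of 13 (11 adjusted over the list alone, median 0.298, camera adjusted p = 1e-21). Mitotic genes were lower in 27 of 28 cases (median -0.373, camera adjusted p = 1.4e-34) and DNA replication genes in 23 of 29 (26 adjusted over the list alone, median -0.263, camera adjusted p = 1.7e-20). AhR targets were higher in 5 of 8 cases (median 0.363, camera adjusted p = 0.00023). NRF2 targets did not differ as a group (6 of 24 higher, 6 lower, 6 and 7 adjusted over the list alone, median -0.0735, camera adjusted p = 0.64). TGF-beta with matrix was higher in 12 of 17 cases (median 0.21, camera adjusted p = 7.4e-09) and NF-kB in 7 of 13 (8 higher and 1 lower adjusted over the list alone, median 0.307, camera adjusted p = 7e-05). ER chaperones were lower in 12 of 20 cases and higher in 1 (14 and 1 adjusted over the list alone, median -0.156, camera adjusted p = 5.4e-08), with DNAJC3 at -0.42. Cholesterol genes were lower in 12 of 24 and higher in 1 (14 and 1 adjusted over the list alone, median -0.147, camera adjusted p = 1.4e-06). PXR and CAR targets were lower in 5 of 11 and higher in 2 (median -0.22, camera adjusted p = 0.00022). In edgeR 3272 genes differed, 1619 higher and 1653 lower, and 2014 did so without Banhasasim-tang replicate 2.

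Bojungikgi-tang and Sayeok-tang differed least at 500 µg/mL, with higher NRF2, ATF4 and ER chaperone genes and lower mitotic genes under Sayeok-tang. ACTA1, which encodes skeletal muscle actin, was higher with Bojungikgi-tang by 1.06 ± 0.0757, at 23.0 ± 1.42 against 11.1 ± 0.609 CPM (SD, n = 3 each; edgeR adjusted p = 6.13e-11). The same held for OSBP2 (0.61), the actin-binding gene TAGLN (0.58), and MT1F (0.76) and MT1G (0.72), both uncertain. IGFBP1 was lower by 0.96 ± 0.105, at 64.9 ± 4.81 against 125.9 ± 5.14 CPM (SD, n = 3 each), SLC16A6 by 0.89, ALDH1L2 by 0.88 and HID1 by 0.85. NRF2 targets were lower with Bojungikgi-tang in 19 of 24 cases (20 adjusted over the list alone, median -0.221, camera adjusted p = 1.5e-49). ATF4 targets were lower in 9 of 27 (16 lower and 1 higher adjusted over the list alone, median -0.135, camera adjusted p = 2.1e-21). ER chaperones were lower in 10 of 20 (13 lower and 1 higher adjusted over the list alone, median -0.142, camera adjusted p = 2e-14). The tRNA synthetases were lower in 6 of 13 (7 adjusted over the list alone, median -0.106, camera adjusted p = 9.5e-10). Mitotic genes were higher in 13 of 28 cases (23 adjusted over the list alone, median 0.161, camera adjusted p = 9.5e-22). Metallothioneins were higher in 5 of 9 and lower in 1 (7 and 1 adjusted over the list alone, median 0.449, camera adjusted p = 1.3e-14). Secreted proteins were higher in 7 of 28 (12 higher and 1 lower adjusted over the list alone, median 0.0934, camera adjusted p = 3.8e-09). DNA replication was higher in 4 of 29 and lower in 1 (9 and 1 adjusted over the list alone, median 0.0541, camera adjusted p = 0.0083). PXR and CAR targets were lower in 2 of 11 cases (5 adjusted over the list alone, median -0.109, camera adjusted p = 0.00038). Autophagy was lower in 8 of 28 (9 lower and 1 higher adjusted over the list alone, median -0.0509, camera adjusted p = 1.3e-05). Acute phase genes were higher in 4 of 13 and lower in 1 (median 0.0553, camera adjusted p = 0.017). CYP1A1 was lower with Bojungikgi-tang by 0.48 ± 0.062 (edgeR adjusted p = 1.7e-05). In edgeR 771 genes differed, 342 higher and 429 lower, and leaving out replicate 2 of Bojungikgi-tang or of Sayeok-tang gave 504 and 510.

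Of the 495 list tests, 80 lost a camera call with an estimated correlation, and every list call above that is printed without such a value held with it. Most of the lost calls are not listed. Adjusted p values at the preset correlation can be far smaller than those with an estimated one. For the difference in dose change of ATF4 targets between Banhasasim-tang and Bojungikgi-tang, given below, the camera adjusted p was 6e-82 at the preset and 8.4e-10 with an estimated correlation. Lists without a call that held in any of the 15 comparisons are given here for Banhasasim-tang at 500 µg/mL against vehicle, with camera adjusted p at the preset correlation. Interferon genes were higher in 3 of 16 cases and lower in 7 (median -0.251, camera adjusted p = 0.29). Heat shock genes were higher in 4 of 14 cases and lower in 7 (5 and 7 adjusted over the list alone, median -0.127, camera adjusted p = 0.25). For p53 targets the counts were 5 higher and 13 lower of 22 (camera adjusted p = 0.97), with a median of -0.239, a mean of 0.00129 and a camera direction up. Hypoxia genes were higher in 12 of 30 cases and lower in 8 (13 and 8 adjusted over the list alone, median 0.10, camera adjusted p = 0.12). PPARA targets were higher in 6 of 20 cases and lower in 11 (6 and 12 adjusted over the list alone, median -0.199, camera adjusted p = 0.44). Gluconeogenesis genes were higher in 5 of 13 cases and lower in 6 (median 0.0225, camera adjusted p = 0.36). Bile acid genes were higher in 3 of 13 cases and lower in 5 (median -0.248, camera adjusted p = 0.74). Nuclear OXPHOS genes were lower in 19 of 37 cases and higher in 6 (20 and 6 adjusted over the list alone, median -0.207, camera adjusted p = 0.034), with an adjusted p = 0.76 with an estimated correlation. Mitochondrially encoded OXPHOS genes were higher in 4 of 13 cases (median 0.311, camera adjusted p = 0.32), and cytosolic ribosomal proteins in 26 of 56 with 7 lower (median 0.128, camera adjusted p = 0.14). Markers of other cell types (1 of 9 higher, 1 lower, median 0.129, camera adjusted p = 0.79), of other epithelial lines (2 of 3 lower, median -0.269, camera adjusted p = 0.33) and of RNA quality (1 of 12 higher, 4 lower, 0 and 2 adjusted over the list alone, median -0.0976, camera adjusted p = 0.67) had no call. Among the list tests given in this report, median, mean and test also differed in sign in 6 that did not pass. These were ATF4 targets with Bojungikgi-tang at 500 µg/mL (mean -0.0229, camera down), and NRF2 targets at 20 µg/mL of Bojungikgi-tang (mean -0.00954, camera up) and Sayeok-tang (mean 0.00744, camera up). The others were AhR targets with Sayeok-tang at 20 µg/mL (mean -0.0294, camera up), NRF2 targets between Banhasasim-tang and Sayeok-tang (mean 0.00166, camera up), and the RNA quality list (mean 0.0253, camera down).

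Sharing of the response between formulas was asked next. At 500 µg/mL against vehicle, Bojungikgi-tang and Sayeok-tang shared 3376 higher genes where 977 were expected from their counts and 3016 lower genes where 876 were expected, and 17 went in opposite directions. The log2 changes of these formulas correlated across genes at r = 0.81, where simulations with shared vehicle libraries and no effect gave a mean of 0.499 and a highest value of 0.569. Part of the excess may come from the shared controls. The simulations held no trend with GC content, which set the real vehicle libraries apart from the extracts. They therefore cannot tell a shared response from that offset. Bojungikgi-tang and Banhasasim-tang correlated at 0.704 (simulated mean 0.434), with 140 genes in opposite directions, and Sayeok-tang and Banhasasim-tang at 0.766 (simulated mean 0.439), with 95. The 3 vehicle libraries were too few to be split between formulas. For the changes from 20 to 500 µg/mL, which share no library, the correlation was 0.435 for Bojungikgi-tang and Sayeok-tang, with 1063 shared higher genes (184 expected) and 899 shared lower genes (147 expected) and 5 in opposite directions. For Sayeok-tang and Banhasasim-tang it was 0.348, with 1125 shared higher (282 expected), 965 shared lower (232 expected) and 62 opposite. For Bojungikgi-tang and Banhasasim-tang it was 0.20, with 710 shared higher (160 expected), 565 shared lower (129 expected) and 79 opposite. These correlations are across genes, which are not independent replicates.

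**Figure D4:**
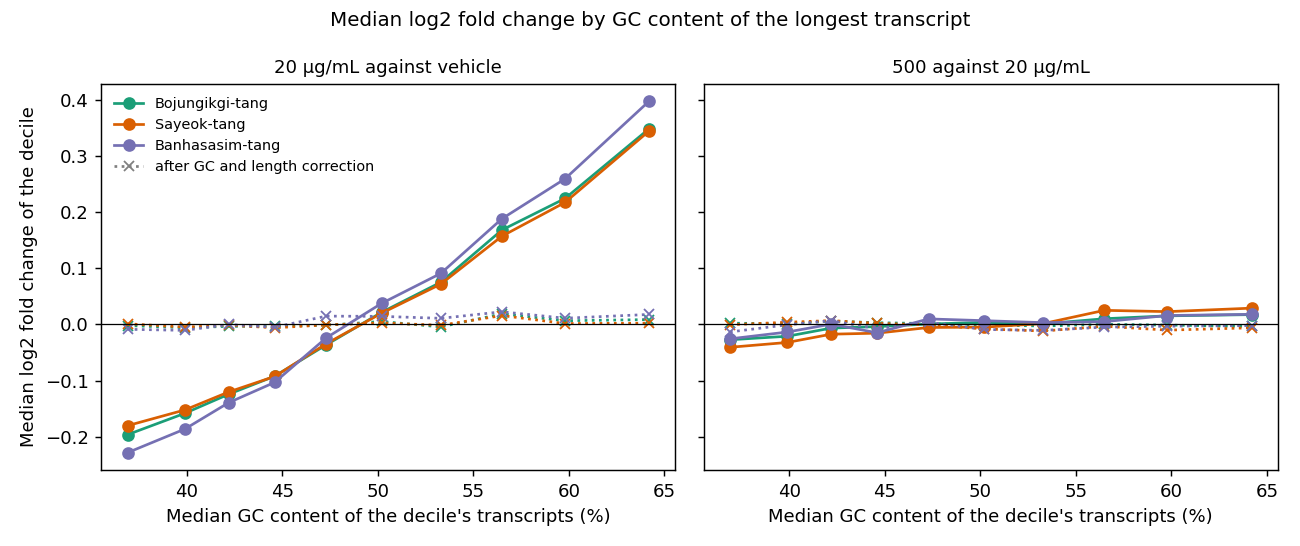
Median log2 change of genes in 10 classes of GC content of the longest transcript, at 20 µg/mL against vehicle (left) and at 500 against 20 µg/mL (right), with circles before and crosses after correction for GC content and length. At 20 µg/mL of Bojungikgi-tang the median went from -0.196 in the class lowest in GC to 0.348 in the highest before correction.

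At 20 µg/mL few genes differed between formulas, in comparisons chosen after the data were seen. Banhasasim-tang differed from Bojungikgi-tang by higher CYP1A1 (2.41 ± 0.082, edgeR adjusted p = 4.6e-15), AKR1B10 (0.32), NQO1 (0.22), SRXN1 (0.24), HKDC1 (0.30) and the drug exporter gene ABCC3 (0.27), and lower SERPINA7 (-0.29) and FGB (-0.20). From Sayeok-tang it differed by higher CYP1A1 (2.35), CYP1A2 (3.56) and ABCC3 (0.34). These genes were chosen after their values were seen. In edgeR 22 genes differed from Bojungikgi-tang, 20 higher and 2 lower, and 14 from Sayeok-tang, 13 higher and 1 lower. DESeq2 called 37 and 44 genes in these comparisons and limma-voom 23 and 14, and 1072 and 1562 genes had an unadjusted p under 0.05 in edgeR where 801 were expected by chance. Between Bojungikgi-tang and Sayeok-tang edgeR called 0 genes, with 436 at an unadjusted p under 0.05 where 801 were expected by chance, and DESeq2 and limma-voom called 0 as well.

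Yijung-tang had 1 library per dose, so its differences from the vehicle mean are given without a test. At 500 µg/mL its values were higher for AhR and NRF2 targets and lower for cholesterol and secreted protein genes. The log2 difference of CYP1A1 was 4.62 at 500 µg/mL, 1.53 at 100 µg/mL and 0.143 at 20 µg/mL. AQP3 was at 1.74, 0.301 and -0.0538 over the same doses, and HES4 at 2.36, 2.65 and 2.46. MYOF (1.70), SLC5A11 (1.69), SOX18 (1.62) and CBARP (1.56), which tunes calcium channels, were higher at 500 µg/mL, as were SLX1A (1.93), SULT1A3 (1.75) and the pseudogene RPS26P19 (1.74), which are uncertain. The calcium-binding gene S100A4 (-1.26), LINC02413 (-1.17), SERPINA7 (-1.13), the ribosomal gene RPS29 (-1.12), the scaffold gene PDZK1 (-1.10), MATN3 (-1.09) and TXNIP (-1.09), an inhibitor of thioredoxin, were lower. The same held for PTMAP5 (-1.62), RN7SL2 (-1.50) and MVP-DT (-1.19), which are uncertain. With prior counts of 0.5 and 5, MYOF was at 1.73 and 1.63 and LINC02413 at -1.18 and -1.14. The median of AhR targets at 500 µg/mL was 1.65 and that of NRF2 targets 0.629, both above all 10000 random lists, and at 100 µg/mL these lists stood at percentiles 98.67 and 45.62. Cholesterol genes (-0.29) and secreted proteins (-0.289) lay below all random lists at 500 µg/mL. Nuclear OXPHOS genes stood at percentiles 0, 0.11 and 0.03 at 500, 100 and 20 µg/mL, so extreme ranks also occurred at every dose. The random lists were not matched on GC content, and each rank rests on 1 library of extract. Metallothioneins had medians of 0.738 at 20 µg/mL, 0.377 at 100 µg/mL and -0.0817 at 500 µg/mL (percentiles 100, 99.89 and 20.21). ATF4 targets (-0.0127, percentile 32) and mitosis (-0.0388, percentile 11.01) stood nearer the middle at 500 µg/mL. MT-RNR1 was at 6506, 5740 and 5525 CPM in the Yijung-tang libraries at 500, 100 and 20 µg/mL, against 4123 ± 199.2 CPM (SD, n = 3) in vehicle. At least 2-fold from vehicle and outside its range were 86 genes at 500 µg/mL (61 higher, 25 lower), 46 at 100 µg/mL and 55 at 20 µg/mL.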

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

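The tests chosen only after a result was seen were those of code prefix and of a growing effect for the vehicle libraries, of polyadenylated RNA and of all mitochondrial transcripts, of matched genes and of grading by dose for metallothioneins, and the splits of the libraries at 20 µg/mL.

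The change between 20 and 500 µg/mL was compared between formulas with an edgeR test of interaction for genes and with camera for lists, at the preset and at an estimated correlation. The change differed in 1489 genes between Banhasasim-tang and Bojungikgi-tang, in 1101 between Banhasasim-tang and Sayeok-tang, and in 161 between Sayeok-tang and Bojungikgi-tang. The lists given are those with a camera adjusted p under 0.05 at both correlations, with median differences of log2 change and, in parentheses, the members that differed in that direction in edgeR. From Bojungikgi-tang, Banhasasim-tang differed by 0.69 for ATF4 targets (24 of 27), 0.529 for immediate early genes (13 of 19), 0.414 for NF-kB (7 of 13), 0.406 for tRNA synthetases (10 of 13), 0.251 for TGF-beta with matrix (8 of 17, 1 opposite), 0.103 for gluconeogenesis (3 of 13), 0.0893 for autophagy (8 of 28) and 0.0853 for NRF2 targets (7 of 24). The differences were -0.475 for mitosis (28 of 28), -0.274 for DNA replication (20 of 29), -0.139 for cholesterol (6 of 24, 1 opposite), -0.126 for AhR targets (1 of 8) and -0.115 for secreted proteins (7 of 28, 3 opposite). From Sayeok-tang it differed by 0.517 for ATF4 targets (22 of 27), 0.511 for metallothioneins (4 of 9), 0.445 for immediate early genes (9 of 19), 0.324 for NF-kB (6 of 13), 0.289 for gluconeogenesis (5 of 13), 0.221 for tRNA synthetases (8 of 13) and 0.196 for TGF-beta with matrix (7 of 17). Negative values there were those of AhR targets (-0.445, 2 of 8), mitosis (-0.319, 23 of 28), PXR and CAR targets (-0.259, 3 of 11), DNA replication (-0.238, 17 of 29), ER chaperones (-0.152, 7 of 20), heat shock (-0.143, 4 of 14) and LXR targets (-0.0958, 3 of 9). The AhR gene CYP1A1 was already higher at 20 µg/mL with Banhasasim-tang, at 100.8 CPM against 19.8 with Sayeok-tang and 19.1 with Bojungikgi-tang. At 500 µg/mL the AhR list was higher with Banhasasim-tang than with either. Sayeok-tang differed from Bojungikgi-tang by 0.251 for NRF2 targets (13 of 24), 0.247 for AhR targets (0 of 8), 0.205 for PXR and CAR targets (1 of 11), 0.139 for ATF4 targets (6 of 27), 0.136 for ER chaperones (6 of 20), 0.113 for tRNA synthetases (0 of 13) and 0.036 for autophagy (1 of 28). It was lower for metallothioneins (-0.344, 2 of 9), mitosis (-0.133, 2 of 28), secreted proteins (-0.0788, 3 of 28) and DNA replication (-0.0407, 0 of 29).

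The vehicle libraries stood apart from every extract group at 20 µg/mL. Bias by GC content and transcript length may account for part of this. The count after the correction was 44.2%, 33.1% and 49.1% of that before it with Bojungikgi-tang, Sayeok-tang and Banhasasim-tang. Of the genes called before it, 30.9%, 22.9% and 34.6% were still called (1900, 1330 and 2236 genes, of which 1827, 1274 and 2159 had the same sign), which leaves the bias open. A library set effect cannot be told apart from treatment, since the vehicle libraries carry a code prefix of their own. Between extract groups of different prefixes at 20 µg/mL, up to 22 genes differed in edgeR and up to 44 in DESeq2. An effect that grows with dose cannot be told apart either. The change of the genes called at 20 µg/mL was at most 1.05 times as large at 100 µg/mL, but 1.08, 1.19 and 1.15 times as large at 500 µg/mL, and choosing genes by their call at 20 µg/mL lowers these ratios. An effect that is full at 20 µg/mL, or a difference in solvent, was not tested.

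Mitochondrial ribosomal RNA was higher with Banhasasim-tang at 500 than at 20 µg/mL. The libraries described as batch D are excluded as the only source of this rise. Without them replicate 2 alone was left at each dose, and MT-RNR1 still rose by 3.45 and MT-RNR2 by 2.56. Every dose of Banhasasim-tang held a library so described, so an offset of that batch would enter 500 and 20 µg/mL alike. A rise of all mitochondrial transcripts is excluded, with a median of 0.0441 over the 13 that encode proteins. Weaker selection of polyadenylated RNA cannot be told apart, since only 3 structural RNAs without a tail were measured (median -0.0197), with standard errors of 0.607 to 0.825. Other explanations were not tested. With Sayeok-tang MT-RNR1 was also higher at 500 than at 20 µg/mL, by less, at 7181 to 9231 CPM against 5109 to 5685 CPM (n = 3 each).

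Metallothioneins were above vehicle at 20 µg/mL and fell between 20 and 500 µg/mL, although for Banhasasim-tang at 20 µg/mL the list call was lost with an estimated correlation (adjusted p = 0.19). Bias by GC content and length is excluded as the main source, since the correction left at least 77.8% of the median against vehicle, and since the genes nearest to the members in GC content and length hardly moved between 20 and 500 µg/mL (medians of -0.015, 0.00491 and 0.00825 with Bojungikgi-tang, Sayeok-tang and Banhasasim-tang). For the difference from vehicle at 20 µg/mL, a library set effect cannot be told apart from treatment, since the vehicle libraries carry their own code prefix. A mere shift of reads among 7 metallothionein genes is excluded for Bojungikgi-tang and Sayeok-tang, where their summed CPM fell by 0.705 and 1.02 log2 units. The sum cannot tell which of these copies fell, and sharing with copies outside it was not tested. For Banhasasim-tang the sum fell by 0.342, less than the fall set beforehand for excluding sharing. Sharing therefore cannot be told apart from a change of the genes there. An effect graded by dose cannot be told apart from other courses either, since the median at 100 µg/mL lay between those at 20 and 500 µg/mL in 2 of 3 formulas, and in Banhasasim-tang it exceeded the value at 20 µg/mL (0.578 against 0.532).

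For groups of 3 libraries, the 10 splits are too few for a share under 0.05. The real grouping gave 7383, 6293 and 6155 genes for Bojungikgi-tang and 8032, 6234 and 5814 for Sayeok-tang at 500, 100 and 20 µg/mL against vehicle, 2433 and 4338 between 500 and 20 µg/mL, and 771 between these formulas at 500 µg/mL, with a highest other count of 1 for Bojungikgi-tang at 500 µg/mL against vehicle and 0 elsewhere. Between Bojungikgi-tang and Sayeok-tang at 20 µg/mL the real grouping and the highest other split gave 0, so all 10 splits reached the real count.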

How the results depend on the processing

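The tests chosen only after the results were seen were those with GC and length correction, without mitochondrial genes, and with the 8 libraries at 20 µg/mL as reference. Each of the 15 counts of changed genes stayed within 1.5 times its value under DESeq2 scaling, the DESeq2 Wald test, limma-voom, both other filters, fits of 2 groups and a fit without mitochondrial genes. After GC and length correction the counts moved to 3459 and 2718 for Bojungikgi-tang at 100 and 20 µg/mL, 3268 and 1925 for Sayeok-tang, and 3170 for Banhasasim-tang at 20 µg/mL. The correction by its construction removes the trend with GC content. Genes called both before and after it numbered 3897 and 2418 at 500 and 100 µg/mL of Bojungikgi-tang. With Sayeok-tang they numbered 4818 and 2183, and with Banhasasim-tang 5638 and 4126. With the 20 µg/mL libraries as reference the counts at 500 and 100 µg/mL were 2900 and 58 for Bojungikgi-tang and 5069 and 264 for Sayeok-tang, and 2278 for Banhasasim-tang at 100 µg/mL. Under this reference the sign changed, in each case with the call lost (adjusted p of 0.16 or more), for AC009086.2 (-0.16) and PTMAP5 (0.16) with Bojungikgi-tang at 500 µg/mL, HES4 (-0.040) and PTMAP5 (0.036) at 100 µg/mL, HES4 (-0.030) and PTMAP5 (0.21) with Sayeok-tang at 500 µg/mL and PTMAP5 (0.17) at 100 µg/mL, and HES4 (-0.11) and PTMAP5 (0.084) with Banhasasim-tang at 100 µg/mL; the cause was not tested. Without the libraries described as batch D, 2347 genes changed between 500 and 20 µg/mL of Banhasasim-tang, with fewer libraries. Leaving out 1 library gave 6391 to 6884, 4874 to 6497 and 5014 to 5612 genes for Bojungikgi-tang at 500, 100 and 20 µg/mL against vehicle, 7231 to 7480, 5243 to 5859 and 4670 to 5140 for Sayeok-tang, and 6662 to 7907, 4351 to 6250 and 4452 to 6014 for Banhasasim-tang. Between doses it gave 1728 to 1940, 3486 to 3912 and 2578 to 3237, and between formulas 504 to 628 (Bojungikgi-tang and Sayeok-tang), 2438 to 3680 (Banhasasim-tang and Bojungikgi-tang) and 2014 to 2925 (Banhasasim-tang and Sayeok-tang). Where 1 Banhasasim-tang library was left in an arm, it was assumed to vary like the other groups. With an estimated correlation 80 of the 495 list tests lost a call. With fry, which does not set a list against other genes, 164 gained and 4 lost a call, and 278 gained one with its mixed test. A fit with the replicate number as a block gave 7415 genes for Bojungikgi-tang at 500 µg/mL and moved no count beyond 1.5 times. Libraries with the same number had a median correlation of -0.0036, and 9 of 27 correlated best with their own number, so the numbers did not pair the libraries. At the depth of these libraries, the smallest simulated changes (0.322 log2 units) were recovered in 42 of 50 genes with 3 libraries of extract. With 2 libraries 38 of 50 were recovered, and changes of 2-fold were recovered in all 50 with either. These genes lay above a floor of expression and all had the same dispersion, so the shares need not hold for the other tested genes.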

Other observations

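No tests were chosen for this part after a result was seen. The summed CPM of 7 metallothionein genes was 779.9 ± 73.0 in vehicle (SD, n = 3), and at 20 µg/mL it was 1405 ± 38.9 with Bojungikgi-tang (SD, n = 3), 1300 ± 49.3 with Sayeok-tang (SD, n = 3) and 1270 ± 51.1 with Banhasasim-tang (SD, n = 2). At 500 µg/mL it was 864.4 ± 82.8, 641.9 ± 61.6 and 1006 ± 136.0 CPM in the same order. The Yijung-tang libraries, which enter no test, had MT1G at 1.29, 0.99 and 0.22 log2 units above vehicle at 20, 100 and 500 µg/mL.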
